A study of Caenorhabditis elegans with 58 samples.

How the data were processed

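Small RNA was sequenced from whole hermaphrodites of the nematode Caenorhabditis elegans, in 58 libraries that the labels place in 15 groups and 3 experiments. Experiment 1 compared wild type with animals carrying the AEDH mutation in both ALG-1 and ALG-2, called double AEDH here, in young adults, L4 larvae and embryos. Experiment 2 compared 6 genotypes in young adults, and experiment 3 compared wild type with each single mutant in embryos. Per the labels' protocols, L4 larvae were grown for 48 h at 20 °C and young adults for 44 h at 25 °C. Embryos, called mixed in the labels, came from growth at 20 °C and were obtained with hypochlorite. The libraries were made with a ligation-based small RNA kit, with size selection on gels after reverse transcription and RNase H treatment, again per the labels' protocols. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

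The deposited table holds estimated counts of reads per miRNA arm, not normalized, for 276 arms of 138 hairpins, 10 spike-in RNAs and 5 summary categories such as reads outside any annotated feature. The authors used cutadapt 3.4, Bowtie2 2.4.4, SAMtools 1.13, HTSeq 0.13.5 and DESeq2, per the submitters' processing notes, and the counting settings are not given in the sources used here. Positions of the arms come from the deposited annotation, which per the file headers is MirGeneDB 2.0 on the ce11 build. Of the table's values, 908 (5.7%) ended in 0.5, always in both arms of a hairpin, and they were rounded to whole numbers. Reads outside annotated features made up 11.9 to 44.6% of all reads per library. These summary categories and the spike-ins were kept out of library sizes and tests, except where spike-ins served as a scaling alternative.

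The arms held 4806008 to 21076791 counts per library, and 231 to 260 arms had at least 1 count. A floor of 3 counts corresponded to 0.142 to 0.624 CPM, the count relative to its library total. The reads come from amplified libraries without molecular identifiers, so floors cover counting error only. All pairs of replicates differed by more than sampling noise, with a chi-square per degree of freedom of at least 131, and each library was counted once. Spike-ins had 608617 to 3114232 counts per library in experiments 1 and 2 and 16 to 48 in experiment 3.

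Each hairpin has a guide arm and a star arm. The star arm was the one marked in the annotation for 132 hairpins and the arm of lower wild-type abundance for the remaining 6. In 14 hairpins the annotated star was the more abundant arm in the mean of all wild-type libraries, among them mir-67, mir-788 and mir-34. This did not hold in every group. In wild-type young adults of experiment 1 the star share was 28.5% for mir-67, 10.5% for mir-788 and 89.6% for mir-34. Near-identical arms (mir-44_3p with mir-45_3p, mir-1829b_3p* with mir-1829c_3p*, and the star arms of mir-789-1 and mir-789-2) are uncertain, because counting could have split or shared their reads, and the mir-788 hairpin is listed at several places in the annotation. Context of hairpins was read from the WBcel235 gene annotation.

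Arms were tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, filterByExpr with a minimum count of 10, robust dispersion) in R 4.3.3, with Benjamini-Hochberg adjustment over the arms tested and a threshold of 0.05. Experiment 1 was fitted per stage, and experiments 2 and 3 with all their groups, which then share 1 estimate of the spread. CPM values are TMM-scaled within each fit, and intervals are 95% intervals from the same model. Star-to-guide ratios were log2 of star count over guide count with 0.5 added to each, for hairpins with a mean count of at least 10 in both arms, tested with limma 3.58.1 (trend, robust). The median of these ratios over hairpins, centred per hairpin, gave 1 value per library, compared by exact two-sided permutation tests. Star arms were set against guide arms with camera at a preset correlation of 0.01, as were 8 lists of related miRNAs fixed beforehand: the mir-35 family, its star arms, the let-7 family with other heterochronic miRNAs, the mir-51, mir-58, mir-2 and mir-44 families, and mir-63 to mir-66 with mir-229. mir-1_3p for muscle and mir-124_3p for neurons served as tissue markers. Correlations between comparisons were taken across arms, which are not independent replicates, and only between comparisons that share no library.

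Named arms followed a rule set before the data were examined: mir-243 in every comparison, up to 12 arms per direction with the largest change among those past the threshold with a mean of at least 10 CPM, up to 6 hairpins per direction for the ratio, and the list members of lowest p. A few arms outside this rule are named as such. The 16 comparisons, their tests, the lists and the main alternatives were chosen before the data were examined. The alternatives were other scalings (DESeq2 size factors, total counts, spike-in totals), other count filters, DESeq2 1.42.0, other sets of libraries in the fit, another pseudocount, another definition of the star arm, other set tests, the replicate number as a block, and leaving out each library in turn. The direct comparison of the single mutants, and a batch term for experiment 3, in which replicates 1 and 2 lay apart from 3 and 4 in their share of reads outside annotated arms, were added after seeing the data. The bounds used to judge 4 of the explanations in the closing section were made stricter, to 2 standard errors, after their values had been seen.

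Replicate numbers in the labels are shared between groups. In the correlation of deviations from group means, every same-numbered pair exceeded 0.1 in 7 comparisons: double AEDH with wild type in young adults of experiment 1 (0.50 to 0.74), L4 larvae (0.25 to 0.66), embryos (0.64 to 0.82) and young adults of experiment 2 (0.18 to 0.49), alg-1 AEDH with wild type (0.31 to 0.76), and the Y47 site deletion with double AEDH against double AEDH (0.24 to 0.55) and against the site deletion alone (0.26 to 0.56). Replicate numbers were taken to pair the libraries in these. For alg-1 AEDH with wild type this is uncertain. There 1 of 4 mutant libraries correlated best with its own number, and differently numbered pairs reached 0.84. The site deletion with wild type (0.08 to 0.37) narrowly missed the bound. Numbers link these groups through the double AEDH genotypes, so pairing of them is uncertain too.

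The tests were run on simulated counts drawn from the means, dispersions and library sizes of 4 comparisons, in 50 data sets each. For the arm test 40 arms were changed per data set, since only 197 to 226 arms were tested. For the ratio test separate draws raised only star arms, each 2-fold. Arms were drawn independently, without the correlation between same-numbered libraries. For double AEDH embryos of experiment 1 (212 arms), edgeR recovered 32.5% of arms changed 1.5-fold, 69.5% of those changed 2-fold and 97.8% of those changed 4-fold, and 4.24% of its calls were false. For L4 larvae (223 arms) these were 25.9, 70.7 and 96.7%, with 5.81% false calls. For the ratio test, a 2-fold change in the star arm was recovered in 27.7% of hairpins in embryos and 21.9% in L4 larvae, with 4.48 and 9.54% false calls. False calls were 5.15% for arms and 5.65% for hairpins in alg-2 AEDH embryos, and 3.93 and 3.97% in young adults of experiment 2, so their share exceeded the nominal threshold in L4 larvae and in alg-2 AEDH embryos, for both tests. Figures were drawn with matplotlib 3.10.9.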

Results

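Argonaute proteins bind miRNAs and can cut a fully paired target through a catalytic tetrad, DEDH in ALG-1 and ALG-2, the main miRNA Argonautes of C. elegans. The series asked what loss of this activity, through an AEDH mutation, does to miRNAs and to their star strands, the strand of each duplex that is normally discarded. It also asked whether target-directed miRNA degradation (TDMD), which needs the ubiquitin ligase receptor EBAX-1, lowers some miRNAs in the double mutant. Experiment 1 had 4 libraries per genotype in young adults and embryos and 3 in L4 larvae, and experiments 2 and 3 had 4 per group. The libraries held 7078431 to 15561291 miRNA counts each in experiment 1, 7671859 to 21076791 in experiment 2 and 4806008 to 6768886 in experiment 3.

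Double AEDH young adults of experiment 1 had 2 star arms that rose and 1 guide arm that fell. mir-63_5p*, from a hairpin outside protein-coding genes (X, 17598785 to 17598849, minus strand, ce11), rose from 265 ± 11.1 to 540 ± 76.4 CPM (SD, n = 4 each), a log2 fold change of 1.03. mir-72_3p* (hairpin at II, 2452854 to 2452919, plus strand, outside protein-coding genes) rose from 86.1 ± 4.82 to 191 ± 50.5 CPM, by 1.15 on the log2 scale. mir-1829a_5p, whose hairpin lies in an intron of gas-1 (X, 15588311 to 15588370, minus strand), fell from 190 ± 30.9 to 87.5 ± 13.3 CPM, a log2 fold change of -1.12. mir-243_3p, the guide arm from an intron of R08C7.12 (IV, 4450798 to 4450861, plus strand), had a log2 fold change of -0.98 (95% interval -1.48 to -0.48) with an edgeR adjusted p of 0.0634, and mir-243_5p, at 5.10 ± 0.660 against 4.40 ± 1.10 CPM, a log2 fold change of 0.21. The edgeR test called 3 of 220 arms (adjusted p 0.00790 to 0.0236), and with replicates as blocks it called 14, of which 4 rose and 10 fell. DESeq2 called 16, DESeq2 size factors in edgeR gave 2 higher and 4 lower arms, and spike-in totals, which moved the median of all arms from 0.05 to 0.23, gave 0 calls. The count was 10 without double AEDH replicate 1, 7 without double AEDH replicate 4, 1 without wild-type replicate 2 or 4, and 0 without wild-type replicate 3.

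Star-to-guide ratios changed in 6 of 90 hairpins of these animals, 5 upward. The star share of the mir-230 hairpin rose from 10.4 ± 1.01% to 24.4 ± 3.02%, that of mir-63 from 13.3 ± 1.23% to 26.1 ± 2.72%, and that of mir-1829a from 33.7 ± 1.59% to 52.4 ± 1.05%. mir-243 (1.18 ± 0.176% to 2.84 ± 1.14%) and mir-72 also rose, and mir-259 fell from 30.0 ± 3.32% to 18.8 ± 2.65% (SD, n = 4 each, limma adjusted p 0.00204 to 0.0281). With replicates as blocks 12 hairpins passed, and 12 passed without double AEDH replicate 1. The median shift over hairpins was 0.21 on the log2 scale (exact permutation p = 0.0286, the smallest possible with 4 against 4; adjusted 0.0572 over 6 comparisons). It was above 0 in 4 of 4 same-numbered pairs, for which the smallest exact p is 0.125. The exact p rose to 0.0571 without double AEDH replicate 1 (shift 0.19) or wild-type replicate 1 (0.21) or 3 (0.20).

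In L4 larvae, 4 star arms rose, and 6 guide arms and 1 star arm fell. mir-237_3p* rose from 28.5 ± 3.43 to 110 ± 50.9 CPM (SD, n = 3 each), and mir-63_5p*, mir-72_3p* and mir-49_5p* rose by 1.31, 1.30 and 0.98 on the log2 scale. mir-1829a_5p fell from 174 ± 28.1 to 67.6 ± 9.64 CPM and mir-243_3p from 588 ± 29.6 to 349 ± 14.3 CPM (log2 fold change -0.75, edgeR adjusted p = 0.0119). mir-2953_3p, mir-1821_3p, mir-230_3p and mir-789-1_5p fell as well, with log2 fold changes of -1.45, -1.07, -0.91 and -0.85, as did mir-1_5p*, the star strand of the muscle miRNA mir-1, at -0.91. Of 223 arms 11 passed in edgeR (adjusted p 0.00586 to 0.0179), 26 with replicates as blocks (11 higher, 15 lower), 21 in DESeq2 and 2 (1 higher, 1 lower) with spike-in totals. Without double AEDH replicate 1, 2 or 3 the count was 2, 6 or 27, and without wild-type replicate 1, 2 or 3 it was 5, 3 or 5, and only mir-63_5p* and mir-1829a_5p passed in each of these.

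Of 91 hairpins in L4 larvae 10 changed their star-to-guide ratio, 7 upward, led by mir-230 (8.77 ± 0.907% star to 24.1 ± 1.37%, SD, n = 3 each), mir-237 and mir-72, with mir-1829a, mir-54 and mir-63 next. Star shares of mir-1, mir-236 and mir-86 fell. With replicates as blocks 17 passed, 15 of them upward, and mir-236 did not (limma adjusted p = 0.0675), and 3, 1, 1 or 5 passed without double AEDH replicate 1 or 2 or wild-type replicate 2 or 3. The median shift was 0.22 (exact permutation p = 0.200, with 0.1 the smallest that 3 against 3 allows), above 0 in 3 of 3 same-numbered pairs.

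Embryos with double AEDH had 16 star arms and 1 guide arm that rose and 7 guide arms that fell. mir-72_3p* rose from 47.5 ± 10.9 to 239 ± 39.9 CPM (SD, n = 4 each), a log2 fold change of 2.33, and mir-54_5p*, from a hairpin of the mir-51 family, from 946 ± 321 to 3652 ± 1247 CPM. mir-67_5p*, mir-70_5p*, mir-57_3p*, mir-80_5p* and mir-49_5p* rose by 1.78, 1.77, 1.68, 1.65 and 1.41 on the log2 scale, and mir-63_5p*, mir-51_3p*, mir-233_5p* and mir-250_5p* by 0.86 to 1.21. The guide arm that rose was mir-788_3p (1.54), in wild-type embryos the less abundant arm of its hairpin. Before TMM scaling it was at 20.5 ± 7.95 CPM there, against 57.4 ± 15.6 for its annotated star. Named guide arms that fell were mir-1829a_5p (-1.58), mir-1821_3p (-0.79), mir-796_5p (-0.69), mir-243_3p (-0.64, edgeR adjusted p = 0.0458), mir-65_5p (-0.47) and mir-72_5p (-0.26), the last from 20711 ± 543 to 17273 ± 950 CPM. The edgeR test called 24 of 212 arms, 62 with replicates as blocks (44 higher, 18 lower), and 12 with spike-in totals (11 higher, 1 lower), which moved the median of all arms from -0.02 to -0.24. The count was 14 or 15 without double AEDH replicate 3 or 4 and 12 without wild-type replicate 3. Of the 18 arms named by rule 8 were lost in at least 1 such fit, among them mir-788_3p, mir-51_3p*, mir-250_5p* and every named guide arm that fell but mir-1829a_5p. mir-243_3p passed only when wild-type replicate 4 was the library left out, with log2 fold changes of -0.73 to -0.45.

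In double AEDH embryos the star-to-guide ratio rose in 16 of 86 hairpins and fell in 1, and either arm can move this ratio. The star share of mir-54 rose from 12.8 ± 4.10% to 40.6 ± 8.65% and that of mir-72 from 0.229 ± 0.0484% to 1.37 ± 0.229% (SD, n = 4 each), and mir-796, mir-795, mir-67 and mir-70 had log2 shifts of 2.87, 1.88, 1.82 and 1.77. The mir-788 star share fell from 74.0 ± 4.35% to 47.3 ± 5.48%. Before TMM scaling its star arm was at 57.4 ± 15.6 CPM in wild type and 53.6 ± 16.8 in double AEDH. Its guide went from 20.5 ± 7.95 to 60.8 ± 24.2 CPM. The mir-1829a ratio rose by 1.57, with a guide log2 fold change of -1.58. Its star arm stayed at -0.05 to 0.23 across 6 double AEDH comparisons, these embryos included. With replicates as blocks 49 hairpins passed. All star arms together made up 1.18 ± 0.274% of miRNA counts in wild type and 2.00 ± 0.592% in double AEDH. The median shift was 0.56 (exact permutation p = 0.0857), it exceeded 0 in 4 of 4 same-numbered pairs (0.43 to 0.78), and the exact p fell to 0.0286 without double AEDH replicate 1 (shift 0.71).

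**Figure D1:**
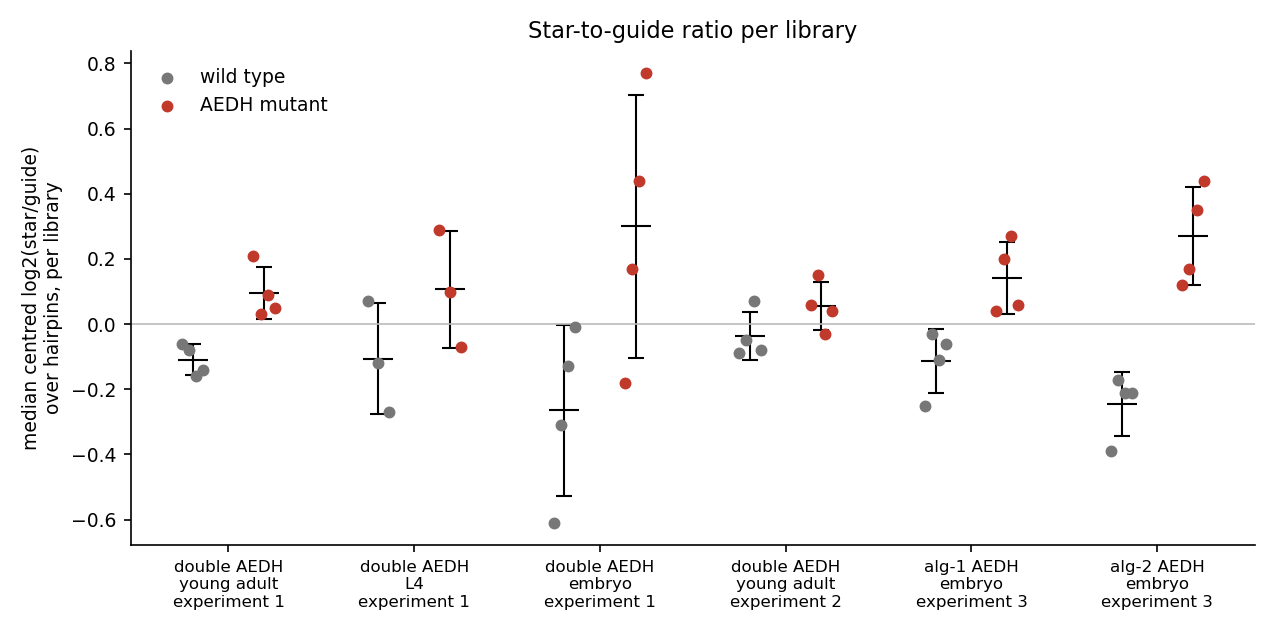
Median log2 star-to-guide ratio over hairpins per library, each hairpin centred within its comparison, for wild type (grey) and AEDH mutants (red) in 6 comparisons, with group means and SD as black bars. The mean difference was 0.56 in double AEDH embryos, 0.52 in alg-2 AEDH embryos and 0.09 in young adults of experiment 2.

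The double AEDH effect was compared between stages with interaction terms over all of experiment 1. In embryos it lay above that in young adults for mir-788_3p (by 2.51), mir-795_3p* (2.07) and mir-72_3p* (1.28), each on the log2 scale, with edgeR adjusted p of 9.57e-04, 9.57e-04 and 0.0357. These 3 arms became 22 with replicates as blocks (21 higher), 1 with spike-in totals, which moved the median of all arms from 0.04 to -0.46, and 5 without replicate 1 of double AEDH embryos or of double AEDH young adults, and mir-72_3p* was lost without at least 1 library. DESeq2 size factors moved that median to -0.09. For mir-788_3p the effects in embryos and young adults had opposite signs. Before TMM scaling it went from 20.5 ± 7.95 to 60.8 ± 24.2 CPM in embryos (SD, n = 4 each). In young adults it went from 138 ± 29.3 to 74.8 ± 14.3 CPM, where edgeR did not call it. Between L4 larvae and young adults edgeR called 0 arms (3 at an unadjusted p under 0.05, DESeq2 0), or 2 with replicates as blocks.

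In young adults of experiment 2, 7 arms rose and 11 fell in double AEDH animals. mir-230_5p, the less abundant arm of its hairpin, rose from 82.6 ± 4.94 to 179 ± 17.9 CPM (SD, n = 4 each), and mir-63_5p*, mir-237_3p*, mir-72_3p*, mir-57_3p*, mir-80_5p* and the let-7 family guide mir-84_5p rose by 1.08, 0.90, 0.76, 0.68, 0.55 and 0.42 on the log2 scale. mir-358_5p* and mir-2953_3p had the largest decreases (-1.31 and -1.24), followed by mir-1_5p* (-0.92), mir-800_3p (-0.91), mir-1829a_5p (-0.88), mir-247_3p (-0.83), mir-784_5p (-0.71), mir-48_3p* (-0.68), mir-54_3p (-0.46) and mir-58a_5p* (-0.43). mir-243_3p fell from 427 ± 139 to 221 ± 66.0 CPM (log2 fold change -0.95, 95% interval -1.54 to -0.36, edgeR adjusted p = 0.0395). Its call was lost without double AEDH replicate 1, 2 or 4 or wild-type replicate 1 or 3 (log2 fold change -0.98 to -0.77, edgeR adjusted p 0.0857 to 0.188), and those of mir-237_3p*, mir-57_3p*, mir-84_5p, mir-784_5p, mir-54_3p and mir-58a_5p* were each lost without at least 1 library. The test covered 226 arms, and spike-in totals gave 4 calls, 2 in each direction.

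Star-to-guide ratios rose in 7 and fell in 2 of 92 hairpins there, with mir-230 (9.66 ± 0.560% star to 21.6 ± 3.32%, SD, n = 4 each), mir-63, mir-237, mir-54, mir-40 and mir-57 higher and mir-1 and mir-48 lower. 5 hairpins passed without wild-type replicate 3. The median shift was 0.09 (exact permutation p = 0.143), above 0 in 3 of 4 same-numbered pairs (-0.10 to 0.20), and 0.12 with p = 0.0286 without wild-type replicate 3. Log2 fold changes of the 2 young adult experiments, which share no library, correlated across 220 arms with Pearson's r of 0.64 (rho 0.59; r = 0.20 with no count filter), and all 18 arms called in experiment 2 had the same sign in experiment 1.

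Across 6 comparisons of double AEDH with its own background that share no library (young adult, L4 and embryo in experiment 1, and wild type, ebax-1 null and Y47 site deletion backgrounds in experiment 2), 195 arms were tested throughout. mir-63_5p* (log2 fold change 0.84 to 1.31) and mir-72_3p* (0.76 to 2.33) rose, and mir-1829a_5p (-1.58 to -0.85) fell, in all 6. mir-57_3p* (0.63 to 1.68) and mir-80_5p* (0.36 to 1.65) rose and mir-1_5p* (-0.92 to -0.50) and mir-1821_3p (-1.07 to -0.60) fell in 4, and mir-230_5p, mir-243_3p and mir-800_3p were called in 3, always in 1 direction. Of 73 star arms 20 lay above 0 in all 6 comparisons and 4 below, and of 122 guide arms 10 lay above and 20 below, where independent signs give 1.56% per direction.

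**Figure D2:**
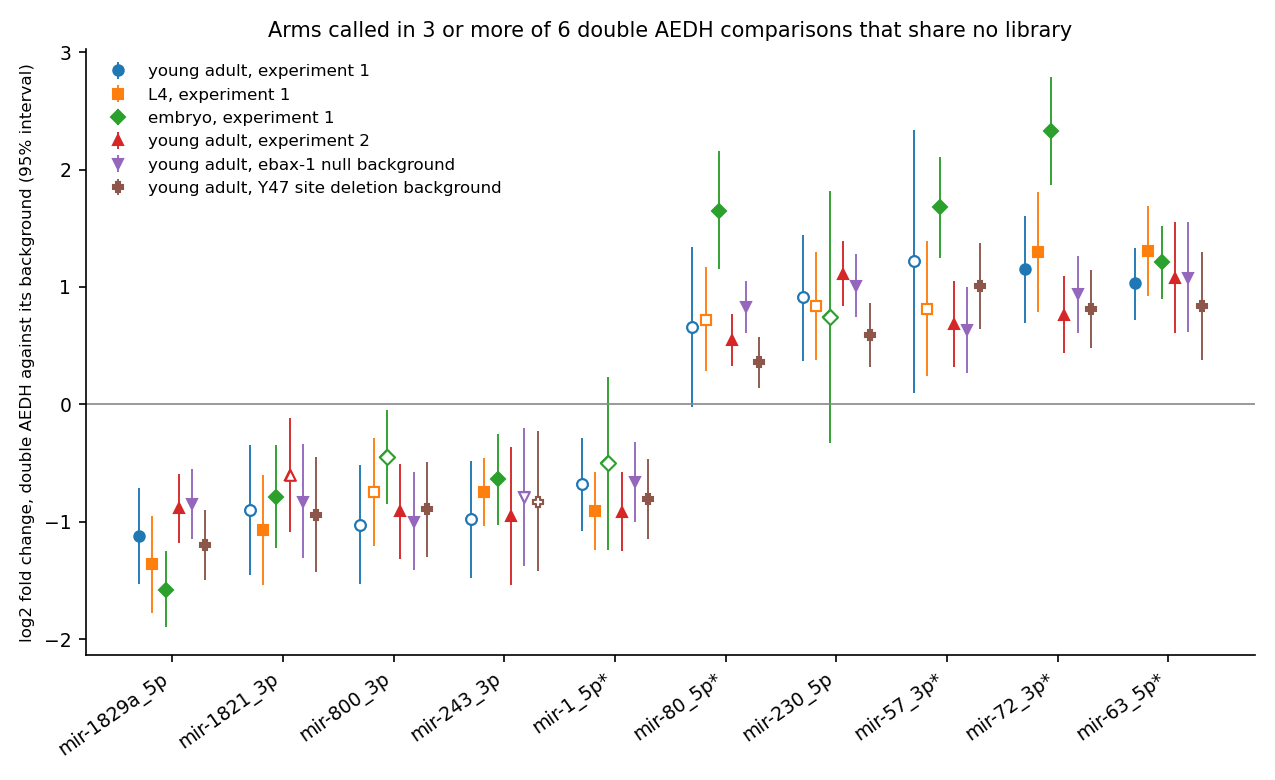
Log2 fold changes with 95% intervals of the 10 arms called in 3 or more of 6 comparisons of double AEDH with its background that share no library, with filled symbols for an edgeR adjusted p below 0.05. mir-63_5p* and mir-72_3p* lay above 0 and mir-1829a_5p below 0, past the threshold, in all 6.

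In embryos of experiment 3, the mutation in ALG-2 alone raised 7 star arms and lowered 1 guide arm. mir-67_5p* rose from 99.9 ± 14.8 to 256 ± 28.8 CPM (SD, n = 4 each), mir-49_5p* from 619 ± 106 to 1539 ± 225 CPM and mir-54_5p* from 2687 ± 323 to 6073 ± 1195 CPM. mir-57_3p* rose from 94.4 ± 23.6 to 207 ± 32.4 CPM, mir-51_3p*, mir-58a_5p* and mir-231_5p* by 1.18, 0.68 and 0.61 on the log2 scale, and mir-1821_3p fell (-0.64). mir-243_3p had a log2 fold change of -0.10 (edgeR adjusted p = 0.655). Of 197 arms 8 passed, against 35 with a batch term for replicates 1 and 2 against 3 and 4, 23 in DESeq2, 14 with total counts and 5 without alg-2 AEDH replicate 3, and mir-58a_5p*, mir-231_5p* and mir-1821_3p were each lost without at least 1 library.

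Star-to-guide ratios changed in 31 of 74 hairpins of alg-2 AEDH embryos, 29 upward. The star share of mir-54 rose from 29.2 ± 3.37% to 53.6 ± 4.70% and that of mir-49 from 15.1 ± 2.96% to 31.2 ± 3.70% (SD, n = 4 each), and mir-67, mir-66, mir-57 and mir-80 rose by 1.16 to 1.54 on the log2 scale. The star share of mir-797 fell from 66.8 ± 5.34% to 38.2 ± 8.38%, and that of mir-4813 fell too. The median shift was 0.52 (exact permutation p = 0.0286, the smallest possible; adjusted 0.0572 over 6 comparisons), 0.42 among replicates 1 and 2 and 0.61 among replicates 3 and 4, with a smallest exact p of 0.0556 for relabelling within these batches. The count of hairpins was 16 or 17 without alg-2 AEDH replicate 3 or 4.

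The mutation in ALG-1 alone raised 1 arm, mir-788_3p, from 54.9 ± 12.6 to 122 ± 8.34 CPM (SD, n = 4 each, log2 fold change 1.15, edgeR adjusted p = 0.00926), and mir-243_3p had a log2 fold change of -0.07. Star shares of mir-75 (25.6 ± 5.46% to 47.5 ± 5.00%), mir-63 (18.5 ± 3.41% to 33.3 ± 5.11%) and mir-67 rose and that of mir-788 fell (58.6 ± 4.86% to 36.7 ± 1.77%), 4 of 74 hairpins. The median shift was 0.26 (exact permutation p = 0.0286, the smallest possible; adjusted 0.0572), 0.27 among replicates 1 and 2 and 0.25 among replicates 3 and 4, above 0 in 4 of 4 same-numbered pairs (exact p = 0.125, the smallest possible), and the exact p was 0.0571 without wild-type replicate 1 (shift 0.22) or 2 (0.26). With replicates as blocks 8 arms and 13 hairpins passed, with the batch term 10 arms and 13 hairpins, without wild-type replicate 2, 3 arms, without alg-1 AEDH replicate 1, 7 hairpins, and DESeq2 called 2 arms.

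Set against each other, in a test added after seeing the data, alg-2 AEDH embryos had higher mir-51_3p* (log2 fold change 1.05), mir-49_5p* (0.82) and mir-67_5p* (0.76) and lower mir-788_3p (-0.92) than alg-1 AEDH embryos, 4 of 197 arms (edgeR adjusted p 0.0114 to 0.0175), or 16 with the batch term. The star-to-guide ratio was higher in 11 of 74 hairpins and lower in 0 (limma, 19 at an unadjusted p under 0.05), led by mir-35, mir-40, mir-54, mir-49, mir-791 and mir-788. The median difference was 0.25 (exact permutation p = 0.0857, n = 4 each), 0.21 among replicates 1 and 2 and 0.28 among replicates 3 and 4. The count of arms fell to 2 without alg-1 AEDH replicate 2 or alg-2 AEDH replicate 3 or 4, and mir-49_5p* and mir-788_3p were each lost in at least 1 such fit. The count of hairpins was 1, 3 or 3 without alg-1 AEDH replicate 2, 3 or 4 and 4, 4, 1 or 0 without alg-2 AEDH replicate 1, 2, 3 or 4, and without alg-1 AEDH replicate 3 the median difference was 0.32 (exact permutation p = 0.0286).

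As a set, star arms lay above guide arms in camera (limma, on the model fitted across all arms) by a median log2 fold change of 0.16 in young adults (adjusted p = 0.00763) and 0.14 in L4 larvae (adjusted p = 0.00285) of experiment 1, 0.52 in its embryos (adjusted p = 4.11e-12), 0.24 in alg-1 AEDH (adjusted p = 7.72e-09) and 0.52 in alg-2 AEDH embryos (adjusted p = 2.30e-12), over 6 comparisons. In young adults of experiment 2 the difference of 0.06 did not pass (limma camera, adjusted p = 0.0987). With an estimated correlation the unadjusted p was 0.0221, 0.238, 0.0621, 1.84e-04, 3.31e-05 and 0.108 in that order, so the calls in L4 larvae and in embryos of experiment 1 were lost. Without double AEDH replicate 1 the difference in L4 larvae was 0.06 and was not called, and in young adults of experiment 2 it was called at 0.07 without double AEDH replicate 3 or 4 and 0.06, called at the threshold, without wild-type replicate 2.

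mir-243 is known to target Y47H10A.5 RNA, and the Y47 site deletion removes its binding site there. Cleavage of this RNA was not measured in these libraries. In young adults of experiment 2, mir-243_3p was at 427 ± 139 CPM in wild type, 338 ± 98.8 in ebax-1 null and 366 ± 76.3 in the site deletion (SD, n = 4 each). Adding double AEDH gave 221 ± 66.0, 196 ± 73.1 and 207 ± 71.8 CPM, log2 fold changes of -0.95, -0.79 (95% interval -1.38 to -0.20) and -0.83 (-1.42 to -0.23), of which the latter pair had edgeR adjusted p of 0.0794 and 0.0985. The interaction of double AEDH with ebax-1 null was 0.16 (-0.67 to 0.99) and with the site deletion 0.13 (-0.71 to 0.96), so a partial loss of the effect was not excluded by either. Within double AEDH animals, mir-243_3p had a log2 fold change of -0.18 (-0.77 to 0.41) with ebax-1 null and -0.10 (-0.69 to 0.49) with the site deletion, neither called by edgeR.

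**Figure D3:**
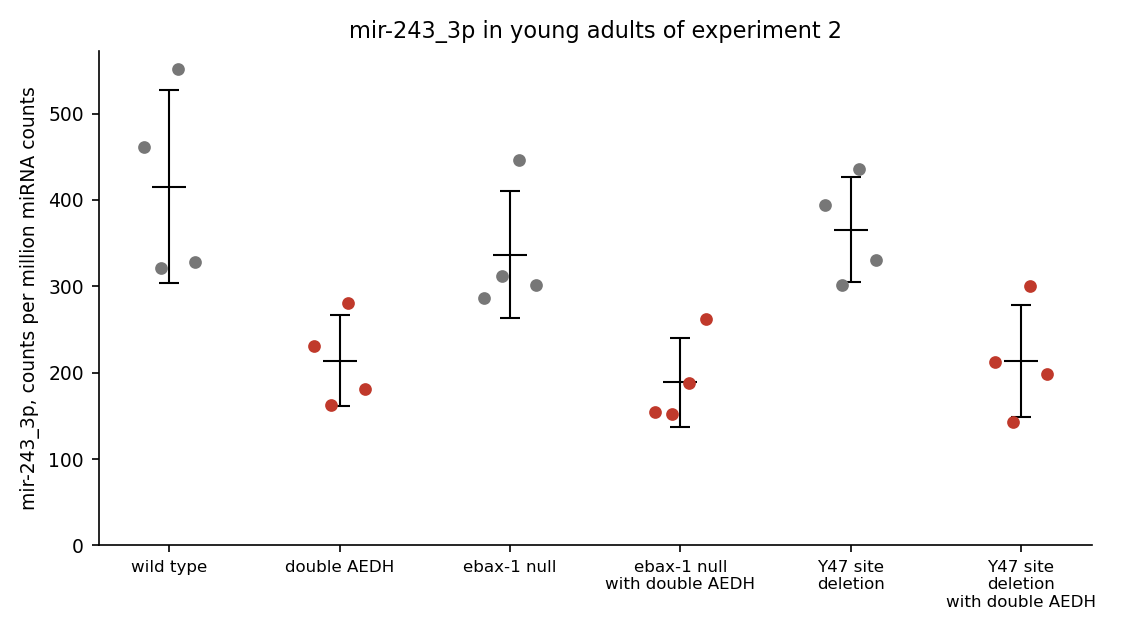
CPM of mir-243_3p, before TMM scaling, in each young adult library of experiment 2, with double AEDH genotypes in red and bars for mean and SD (n = 4). Means were 416, 337 and 365 in wild type, ebax-1 null and Y47 site deletion, and 214, 189 and 214 in the same backgrounds with double AEDH.

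Other arms lowered by double AEDH were also compared across backgrounds. In ebax-1 null animals, adding double AEDH changed 25 of 226 arms, 16 up and 9 down. mir-237_3p* (1.48), let-7_3p* (1.18), mir-63_5p* (1.08), mir-230_5p (1.01) and mir-72_3p* (0.94) led the increases on the log2 scale among arms with a mean of at least 10 CPM, and mir-253_3p (-1.66), mir-1829a_5p (-0.85), mir-1821_3p (-0.83), mir-83_5p* (-0.74) and mir-247_3p (-0.71) the decreases. Below that mean, outside the rule for naming, mir-2953_3p (-2.02) and mir-800_3p (12.4 ± 2.38 to 6.20 ± 0.858 CPM, SD, n = 4 each) fell too. mir-253_3p was at 1574 ± 1337 CPM in ebax-1 null (SD, n = 4). In the site deletion background 16 arms changed, 7 up and 9 down, with mir-57_3p* (1.01) and mir-1829a_5p (-1.20) at the extremes of those with a mean of at least 10 CPM. The 10 arms called lower in experiment 1 had median double AEDH effects of -0.74, -0.73 and -0.68 in the wild type, ebax-1 null and site deletion backgrounds of experiment 2, with 10, 10 and 9 arms below 0 and 4 called in each. Spike-in totals gave 2 higher and 9 lower arms in ebax-1 null, moving the median of all arms from 0.01 to -0.22, and 0 and 2 in the site deletion, total counts gave 13 and 12 in ebax-1 null, and only the compared groups in the fit gave 12 calls there. The counts were 16, 15 and 16 without replicate 1, 2 or 3 of ebax-1 null with double AEDH, and 10 in the other background without Y47 site deletion replicate 4. Of the arms named for ebax-1 null, let-7_3p*, mir-253_3p, mir-1821_3p and mir-247_3p were each lost without at least 1 library.

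The interaction of ebax-1 null with double AEDH passed for the near-identical arms mir-1829b_3p* (1.19) and mir-1829c_3p* (1.20), which fell in ebax-1 null (-0.88 and -0.92). mir-1829b_3p* was at 178 ± 21.7 CPM in wild type, 97.0 ± 17.1 in ebax-1 null and 176 ± 42.4 in ebax-1 null with double AEDH (SD, n = 4 each). The interaction was lost without double AEDH replicate 1 or 2, ebax-1 null with double AEDH replicate 3 or 4, ebax-1 null replicate 4 or wild-type replicate 3, 1 arm was left without ebax-1 null replicate 2, and spike-in totals, which moved the median of all arms from -0.04 to -0.28, gave 1 lower arm. For the site deletion, edgeR called 0 interaction arms (11 at an unadjusted p under 0.05, DESeq2 0).

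Loss of EBAX-1 alone gave the largest changes of experiment 2. mir-788_5p* rose from 29.6 ± 1.04 to 535 ± 71.0 CPM (SD, n = 4 each), a log2 fold change of 4.17, and mir-42_3p, a member of the embryonic mir-35 family (hairpin at II, 11889823 to 11889891, plus strand, outside protein-coding genes), from 129 ± 34.6 to 1682 ± 441 CPM (3.71). mir-247_3p (2.93), mir-253_3p (2.39), mir-230_3p (1.97), mir-34_5p* (1.41), mir-244_5p (1.19), let-7_3p* (1.07), mir-239a_3p* (0.94), mir-83_5p* (0.83), mir-67_5p* (0.80) and mir-233_3p (0.74) rose too. mir-2210_3p (-1.38), mir-795_3p* (-1.03), the arms of mir-1829b and mir-1829c (-0.92 to -0.87), mir-70_3p (-0.83), mir-790_5p (-0.83), mir-61_5p* (-0.83), mir-795_5p (-0.73) and the mir-1829a arms (-0.72 and -0.71) fell. mir-243_3p had a log2 fold change of -0.34 (95% interval -0.92 to 0.25). The mir-2 family member mir-43_3p rose by 3.14, and mir-797_5p*, chosen after its values were seen, by 2.37. The edgeR test called 49 of 226 arms, 23 higher and 26 lower, and with spike-in totals, which moved the median of all arms from -0.01 to 0.75, it called 107, all higher, and mir-795_5p (0.07), both mir-1829a arms (0.03 each) and mir-243_3p (0.36) lay above 0. Spike-ins made 7.37 ± 2.2 counts per 100 miRNA counts in ebax-1 null and 11.7 ± 1.84 in wild type. The count was 28 without ebax-1 null replicate 2 and 32 without wild-type replicate 1, and let-7_3p*, mir-67_5p*, mir-233_3p, mir-790_5p and both mir-795 arms were each lost without at least 1 library.

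In the double AEDH background, ebax-1 null changed 36 arms, 16 up and 20 down. mir-788_5p* (4.15), mir-42_3p (3.41), mir-247_3p (3.04), let-7_3p* (2.05) and mir-230_3p (1.71) rose most among named arms, and mir-795_5p (-0.98), mir-785_3p (-0.86), the neuronal lsy-6_3p (-0.85), mir-1822_3p (-0.83) and mir-60_3p (-0.70) fell. Both effects of ebax-1 null correlated across 226 arms (Pearson's r = 0.81, rho 0.67), and they shared 13 higher and 13 lower arms, against 1.63 and 2.30 for independent lists. Spike-in totals gave 26 calls, all higher, with a median of all arms of 0.47 in place of -0.04. Without replicate 1, 3 or 4 of double AEDH the count was 19, 20 or 20, and without replicate 1, 2 or 3 of ebax-1 null with double AEDH it was 22, 21 or 21, and lsy-6_3p was lost in at least 1 such fit.

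**Figure D4:**
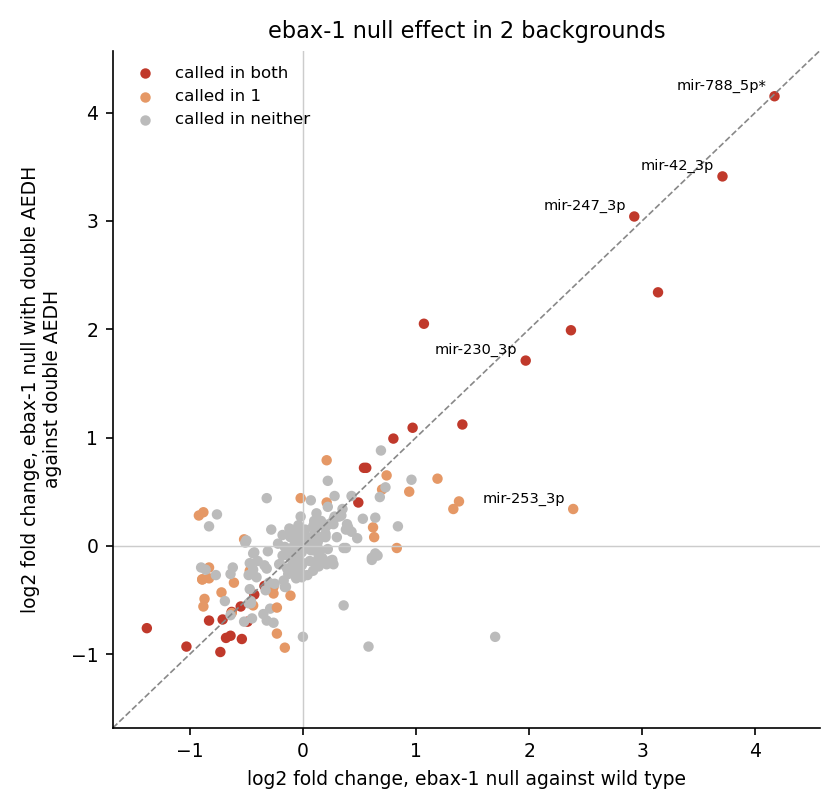
Log2 fold change of each arm in ebax-1 null against wild type (horizontal) and in ebax-1 null with double AEDH against double AEDH (vertical), young adults of experiment 2, coloured by how many of the comparisons called it, with equality dashed. mir-788_5p* and mir-42_3p lie at the far end of both axes, at 4.17 and 3.71 without and 4.15 and 3.41 with double AEDH.

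The Y47 site deletion changed 0 arms by edgeR against wild type (18 at an unadjusted p under 0.05, DESeq2 0) and 0 within double AEDH (7 at an unadjusted p under 0.05, DESeq2 0). mir-243_3p had a log2 fold change of -0.22 (95% interval -0.81 to 0.36) against wild type. Without Y47 site deletion replicate 1, 1 arm passed against wild type.

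Of the 8 lists in 7 comparisons, 3 tests passed camera after adjustment over 56. All 8 star arms of the mir-35 family, which is abundant in embryos, lay above 0 in double AEDH embryos (median 0.56, adjusted p = 0.0232, 2 called and 4 called adjusted over the list alone, mir-42_5p* at 0.79 and mir-38_5p* at 0.63). All 8 lay above 0 in alg-2 AEDH embryos too (median 0.92, adjusted p = 0.00157, 0 called by edgeR and 6 adjusted over the list alone, with mir-38_5p* at 1.00). Star arms of all hairpins had medians of 0.44 in double AEDH and 0.31 in alg-2 AEDH embryos. Since camera set the list against all other arms, guides included, these tests do not separate the family from star arms in general. The mir-44 family rose in ebax-1 null (median 0.55, adjusted p = 0.0232), with mir-247_3p and the near-identical mir-44_3p (0.56) and mir-45_3p (0.54) higher, 3 called and 3 adjusted over the list alone, and mir-61_3p at -0.28. With an estimated correlation the adjusted p was 0.994, 0.994 and 0.850, so none of the 3 was kept. The guide arms of the mir-35 family had a median of -0.60 in double AEDH young adults of experiment 2 (7 of 8 below 0, adjusted p = 0.0783) and the let-7 list a median of -0.32 in double AEDH embryos (0 of 8 above 0, adjusted p = 0.532). The mir-51, mir-58 and mir-2 families and mir-63 to mir-66 with mir-229 passed in 0 of the camera tests (0 at an unadjusted p under 0.05, adjusted p 0.532 to 0.993). Muscle mir-1_3p (-0.24 to 0.22) and neuronal mir-124_3p (-0.46 to 0.52) were not called by edgeR in any of the 7 comparisons. The neuronal marker was rare, with stage means of 4.66 to 7.81 CPM before TMM scaling in wild type of experiment 1. Its SE reached 0.37, in young adults of experiment 2, so a change in neuronal content was not excluded.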

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

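Tests of the spike-in pattern, of the catalytic residues and of degradation, and the counts of splits in all comparisons but that of alg-2 AEDH with alg-1 AEDH, were chosen only after the result was seen. The comparison of alg-2 AEDH with alg-1 AEDH and the batch term were also added then. The bounds for 4 tests (more miRNA, degradation through EBAX-1 as most of the cause, arms higher in ebax-1 null, side of the star arm) were made stricter after their values had been seen.

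In 13 of 201 groups of 4 libraries, 1 library lay far from the others by the gap over the range, where chance gives 10.1. For miRNA counts the gap was 0.858 of the range for Y47 site deletion replicate 1, 0.929 for replicate 2 of ebax-1 null with double AEDH and 0.866 for wild-type embryo replicate 1 of experiment 3. For spike-ins per 100 miRNA counts it was 0.953 for Y47 site deletion replicate 4 and 0.900 for ebax-1 null replicate 3. For CPM of an arm it was 0.967 for mir-230_5p in double AEDH replicate 1 and 0.851 for mir-358_5p* in wild-type replicate 1, both young adults of experiment 2. In embryos of experiment 3 it was 0.875 for mir-243_3p in alg-1 AEDH replicate 1, 0.881 for mir-67_5p* in wild-type replicate 1 and 0.892 for mir-51_3p* in wild-type replicate 4. In ebax-1 null it was 0.848 for mir-243_3p in replicate 3, 0.857 for mir-244_5p in replicate 2 and 0.916 for mir-1829b_3p* in replicate 4.

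Effects differed between groups for 5 arms by interaction tests. The double AEDH effect in ebax-1 null exceeded that in wild type by 1.19 for mir-1829b_3p* and 1.20 for mir-1829c_3p*. The effect in embryos lay above that in young adults by 2.51 for mir-788_3p, 2.07 for mir-795_3p* and 1.28 for mir-72_3p*. For mir-788_3p the effects had opposite signs. Embryos and young adults also differed in growth temperature. Chance was not excluded for either set: 5 of 100 drawn splits gave as many arms in each. The highest other count was 69 against 2 and 16 against 3, and what gave these high counts was not tested. For the interaction with the site deletion and for L4 larvae against young adults 0 arms were called by edgeR (11 and 3 at an unadjusted p under 0.05, DESeq2 0), and all 100 splits gave as many, at most 8 and 12. Libraries of experiment 3 held up to 48 spike-in counts, which were not used.

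Star arms were higher in double AEDH embryos of experiment 1. The intercept of their log2 fold changes on the wild-type change from embryo to L4 was 0.48 (SE 0.07 over 85 star arms), close to their median of 0.44. The labels call the embryos mixed, and that change does not measure age within embryos. A difference in embryo age between the groups was therefore not excluded. Counting noise of rare arms was argued against by a shift of 0.61 in hairpins with the more abundant star arms and 0.29 in the others. Loss of the catalytic residues is a candidate explanation, as the shift was 0.52 in alg-2 AEDH and 0.26 in alg-1 AEDH embryos against other wild-type libraries. The difference of star and guide arms as a set was as large in 6 of 35 splits (0.52, highest other 0.69), so chance was not excluded for it. Replicate numbers pair these embryos, and among the 7 other splits that part as many pairs the highest was 0.44, with too few such splits for a share under 0.05. All 4 same-numbered pairs had a median shift above 0 (0.43 to 0.78). For arms (24, highest other 6) and hairpins (17, highest other 4) the real split alone, 1 of 35, gave as many.

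Arms lower in double AEDH may be lowered by target-directed degradation. Degradation of mir-243 through the deleted site as the whole cause of its decrease was argued against, since mir-243_3p had a double AEDH effect of -0.83 (SE 0.29) in the site deletion background and -0.95 in wild type. Degradation through EBAX-1 as the whole cause was argued against as well, since 95% intervals lay below 0 for 8 of 10 arms in ebax-1 null. The 10 arms had a median effect of -0.73 there and -0.74 in wild type. The SE of 0.19 in ebax-1 null is over arms, which share libraries and are not independent replicates. Whether degradation through EBAX-1 accounts for most of the effect stays open. The spread of that median over arms reaches past the bound of 0.5 of the wild-type value. A part played by either route stays open too.

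With spike-in totals all 107 called arms were higher in ebax-1 null. Relative to spike-ins, reads outside annotated arms differed by 0.55 on the log2 scale (exact permutation p = 0.114, n = 4 each) and miRNA counts by 0.69 (exact p = 0.0571), and miRNA counts relative to those reads by 0.15 (exact p = 0.314). Within double AEDH, ebax-1 null gave 0.39 for reads outside annotated arms and 0.52 for miRNA counts relative to spike-ins (exact p = 0.0571 each). There miRNA counts relative to those reads differed by 0.13 (exact p = 0.257). Less added spike-in and more miRNA relative to other small RNA cannot be told apart, because the spread between 4 libraries per group is wide. Less added spike-in and more small RNA of all kinds would give the same ratios whatever the spread, so these values cannot separate them.

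Splits of the libraries were counted for each remaining result. With 4 against 4 libraries a share of 1 of 35, the real split alone, is the smallest possible. It was not adjusted over the results counted, so it is not taken to exclude chance. In young adults of experiment 1, 2 of 35 splits gave as many arms (3, highest other 17, from parting replicates 1 and 4 from 2 and 3, a structure of the samples) and 3 of 35 as large a star arm difference (0.16, highest other 0.19), so chance was not excluded, while 1 of 35 gave as many hairpins (6, highest other 1). In L4 larvae 10 splits are too few for a share under 0.05: 1 gave as many arms (11, highest other 0), 1 as many hairpins (10, highest other 0) and 4 as large a star arm difference (0.14, highest other 0.25). In young adults of experiment 2, 1 of 35 gave as many arms (18, highest other 4) and 1 of 35 as many hairpins (9, highest other 2). As large a star arm difference came from 9 of 35 (0.06, highest other 0.08), so chance was not excluded for it. In alg-1 AEDH embryos 3 of 35 gave as many arms (1, highest other 98) and 4 of 35 as many hairpins (4, highest other 6), so chance was not excluded. The count of 98 came from parting replicates 1 and 2 from 3 and 4, where the batch term gave 10. As large a star arm difference came from 1 of 35 (0.24, highest other 0.2). In alg-2 AEDH embryos the real split alone gave as many arms (8, highest other 0) and hairpins (31, highest other 1). The same held for the star arm difference (0.52, highest other 0.42). Between the single mutants it alone gave as many arms (4, highest other 1) and hairpins (11, highest other 1). There 5 of 35 gave as large a star arm difference (0.18, highest other 0.29). For experiment 3 the 35 splits ignore the batches, and relabelling within batches has a smallest exact p of 0.0556. Chance was therefore not excluded in these embryos.

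In the other comparisons of experiment 2 with called arms the real split alone, 1 of 35, gave as many. These were ebax-1 null against wild type (49 arms, highest other 22) and the site deletion with double AEDH against the site deletion (16, highest other 0). The others were ebax-1 null with double AEDH against double AEDH (36, highest other 6) and against ebax-1 null (25, highest other 19). For the site deletion against wild type and within double AEDH edgeR called 0 arms (18 and 7 at an unadjusted p under 0.05, DESeq2 0), as all 35 splits did or exceeded, at most 1 and 0. Where replicate numbers pair the libraries, the 7 splits in experiments 1 to 3 that part as many pairs as the real one gave 0 arms for groups of 4, as did the 3 in L4 larvae. For star arms as a set these splits gave at most 0.11 in young adults of experiment 1, 0.08 in L4 larvae, 0.2 in alg-1 AEDH embryos and 0.06, as large as the real split, in young adults of experiment 2. Splits that part as many pairs are too few for a share under 0.05 in any of these comparisons. Shares of 1 of 35 in paired libraries rest on all 35 splits, which ignore the pairing, so they do not exclude chance.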

How the results depend on the processing

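The batch term and everything on alg-2 AEDH against alg-1 AEDH were chosen after seeing the data. Of 640 alternative values of the counts, shifts and set tests 518 kept their direction and side of the threshold, 96 moved, 17 weakened and 9 strengthened. Of 2863 for named arms 2356 were the same, 446 weaker, 15 stronger and 46 reversed. Where no cause is given, the cause was not tested. Rare arms limit the depth: a floor of 3 counts was up to 0.624 CPM, and spike-in scaling was not run in experiment 3, whose libraries held too few spike-in counts.

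Called arms moved as follows. DESeq2 gave 16 in young adults of experiment 1, 21 in L4 larvae, 2 in alg-1 AEDH, 23 in alg-2 AEDH and 7 between the single mutants. DESeq2 size factors gave 6 and all libraries of experiment 1 in the fit 10 in young adults of experiment 1. Total counts gave 3 in alg-1 AEDH and 14 in alg-2 AEDH, and a minimum count of 100 gave 2 in alg-1 AEDH. With spike-in totals there were 0 in young adults of experiment 1 by edgeR (30 at an unadjusted p under 0.05 with TMM, DESeq2 16), 2 in L4 larvae, 12 in embryos, 4 in young adults of experiment 2, 107 in ebax-1 null, 11 for double AEDH in ebax-1 null, 2 for it in the site deletion, 1 for the ebax-1 interaction and 1 for the embryo stage interaction. Only the compared groups in the fit, with fewer samples, gave 12 for double AEDH in ebax-1 null. The batch term gave 10 in alg-1 AEDH, 35 in alg-2 AEDH and 16 between the single mutants. Replicate block, for libraries paired by number, gave 14 in young adults of experiment 1, 26 in L4 larvae, 62 in embryos, 8 in alg-1 AEDH, 22 and 2 for the embryo and L4 stage interactions. Numbers do not pair alg-2 AEDH with wild type (-0.04 to 0.66) or alg-1 AEDH (-0.09 to 0.67), where the block gave 29 and 16. Nor do they pair ebax-1 null with wild type (-0.41 to 0.30), or ebax-1 null with double AEDH with double AEDH (-0.25 to 0.38) or ebax-1 null (-0.49 to -0.07), where the block gave 53, 44 and 27. The site deletion with wild type (0.08 to 0.37) narrowly missed the bound, and pairing there is uncertain. The block gave 0 arms there by edgeR (18 at an unadjusted p under 0.05 without it, DESeq2 0). The block moved no other count by more than 1.5 times.

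For hairpins, the replicate block gave 12 in young adults of experiment 1, 17 in L4 larvae, 49 in embryos and 13 in alg-1 AEDH, the batch term 13 and a pseudocount of 5 gave 7 in alg-1 AEDH. Median shifts as pairs stayed at 0.21, 0.26 and 0.52 in young adults of experiment 1, alg-1 AEDH and alg-2 AEDH (exact p = 0.125, the smallest possible), and within batches at 0.26 and 0.52 (exact p = 0.0556, the smallest possible). A mean count of at least 100 gave 0.32 between the single mutants (exact p = 0.0286). With an estimated correlation star arm differences of 0.14 in L4 larvae (p = 0.238) and 0.52 in embryos (p = 0.0621) were not called, nor were list medians of 0.56 and 0.92 for mir-35 star arms (adjusted p = 0.994 each) and 0.55 for the mir-44 family (adjusted p = 0.850). fry sets star arms against no change, so it does not test their difference from guide arms: it did not call them in L4 larvae (star arm median 0.12, difference 0.14) and called them in young adults of experiment 2 (star arm median 0.11, difference 0.06, not called in camera). With spike-in totals camera called that difference (0.05). The correlation of both young adult experiments was 0.75 at a minimum count of 100 and 0.20 with no filter.

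In ebax-1 null mir-243_5p was at 0.03 in DESeq2, 0.02 with DESeq2 size factors, no filter or only the compared groups, 0.01 with total counts and 0.76 with spike-in totals, which also turned mir-243_3p to 0.36, mir-795_5p to 0.07, and mir-1829a_3p* and mir-1829a_5p to 0.03. Spike-in totals gave mir-243_3p 0.33 for ebax-1 null within double AEDH, -0.03 in the ebax-1 interaction and -0.05 in the embryo stage interaction, and mir-243_5p -0.08 for double AEDH in ebax-1 null and -0.17 in the ebax-1 interaction. DESeq2 gave mir-243_3p 0.00 between the single mutants.

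Leaving out 1 library at a time, called arms ranged over 0 to 10 in young adults of experiment 1, 2 to 27 in L4 larvae, 12 to 32 in embryos, 1 to 3 in alg-1 AEDH, 5 to 10 in alg-2 AEDH, 28 to 50 in ebax-1 null, 0 to 1 in the site deletion, 19 to 29 for ebax-1 null within double AEDH, 15 to 30 and 10 to 16 for double AEDH in ebax-1 null and in the site deletion, 0 to 3 for the ebax-1 interaction, 2 to 5 for the embryo stage interaction and 2 to 6 between the single mutants. Hairpins ranged over 4 to 12 in young adults of experiment 1, 1 to 12 in L4 larvae, 5 to 10 in young adults of experiment 2, 3 to 7 in alg-1 AEDH, 16 to 26 in alg-2 AEDH and 0 to 8 between the single mutants. Shifts ranged over 0.18 to 0.23, 0.39 to 0.71 and 0.07 to 0.13 in young adults of experiment 1, embryos and young adults of experiment 2, 0.18 to 0.30 in alg-1 AEDH and 0.23 to 0.32 between the single mutants, and star arm differences over 0.06 to 0.20 in L4 larvae and 0.02 to 0.07 in young adults of experiment 2. mir-243_5p ranged over -0.09 to 0.20 for double AEDH in wild type, -0.13 to 0.10 for ebax-1 null, -0.24 to 0.06 for the site deletion, -0.01 to 0.28 for ebax-1 null within double AEDH and -0.07 to 0.28 in the ebax-1 interaction, all in experiment 2. mir-243_3p ranged over -0.18 to 0.01 in alg-1 AEDH, -0.42 to 0.06 and -0.26 to 0.14 for ebax-1 null and the site deletion within double AEDH, -0.12 to 0.42 and -0.11 to 0.35 in the interactions and -0.09 to 0.06 between the single mutants.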

Other observations

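The tests below were planned before their results were seen, except the description of wild-type stages, but the bounds for judging the ebax-1 null arms and the side of the star arm were made stricter afterwards.

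In wild-type animals of experiment 1, miRNA families took different shares of miRNA counts by stage. The mir-35 family, essential in embryos, made up 50.4 ± 1.62% in embryos (SD, n = 4), 0.634 ± 0.0542% in L4 larvae (n = 3) and 7.77 ± 2.13% in young adults (n = 4). The let-7 family with other miRNAs of developmental timing made up 0.0414 ± 0.0187%, 7.73 ± 0.431% and 6.46 ± 0.343% in the same stages, and the bantam-related mir-58 family 6.39 ± 0.472%, 15.3 ± 0.553% and 18.2 ± 1.18%. The mir-51 family made up 12.5 ± 1.15%, 10.7 ± 0.666% and 7.75 ± 0.216%. These shares were not tested, and stages also differed in growth temperature and collection.

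A hypothesis was that guide arms raised in ebax-1 null are lowered by double AEDH. In young adults of experiment 1 these 13 arms had a median double AEDH log2 fold change of 0.18, with 3 below 0, against 0.00 for 116 other guide arms (permutation p = 0.0510), so their median lay on the opposite side of what was proposed and the test did not pass.

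The shift in alg-2 AEDH embryos was also computed without the 8 hairpins of mir-35 to mir-42, which gave 0.47 against 0.52 with them (exact permutation p = 0.0286, the smallest possible, n = 4 each). In double AEDH embryos of experiment 1 the median shift of star arms on the 5p side exceeded that on the 3p side by 0.10 (0.53 over 58 and 0.43 over 28 hairpins, permutation p = 0.627), which leaves a difference between sides open.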
